A study of Bos taurus with 15 samples.

How the data were processed

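Poly(A) RNA was sequenced from bovine (Bos taurus) blastocysts at day 7 in 3 groups of 5 libraries. The groups were blastocysts collected in vivo, blastocysts cultured after manual removal of the cumulus cells, and blastocysts cultured after automatic removal of the cumulus cells. Per the labels' protocols, cumulus cells were removed from zygotes, culture was in SOF medium, and libraries were made with a stranded mRNA kit and adaptors carrying molecular identifiers. The labels' design gives 5 blastocysts per group, as many as libraries, and their protocol 50-100 ng of total RNA for a library; they do not say outright whether a library holds 1 blastocyst or a pool. The labels do not say that the libraries of a group came from separate cultures, donors or days, so p-values measure only the spread between these libraries, which may be technical.

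The authors deposited 1 table of estimated counts per gene, given as whole numbers and not scaled to a common total. FastQC, fastp and kallisto are named, without versions or roles, per the submitters' processing notes; because kallisto estimates counts, the values were treated as estimated counts. The transcript set, the genome build and the handling of molecular identifiers are not given in the sources used here, so no coordinates are printed. Genes with close paralogs (PAG2, KRT18 and other members of gene families) share reads that such estimation divides, so their values are less certain. The table held 17259 genes, of which 17059 matched a symbol of the ARS-UCD2.0 annotation, which was used for names alone. It also held 1 line without a gene name, which contained 0 values and was left out. No libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of at least 191. Columns were assigned to samples by the library names in the labels.

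Library totals ranged from 17.96 to 41.97 M counts (1 M is 1e6 counts), with a median of 27.6 M. Differential expression was tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 (robust estimateDisp and glmQLFit, glmQLFTest), with TMM factors and the genes kept by filterByExpr (11578 of 17259), after rounding to whole numbers, which changed no value. All 15 libraries entered 1 fit with a mean per group. The contrasts were automatic against manual, the mean of automatic and manual against in vivo, and each in vitro group against in vivo. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were the absolute fold change divided by the square root of F. CPM values use the TMM-scaled library sizes. By the 95% intervals of that fit, 24.0% of genes in automatic against manual and 26.8% in the mean of automatic and manual against in vivo were bounded within 4-fold.

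The gene lists, 23 in number with 825 symbols (753 in the table), cover embryonic lineages, other cell types that might accompany an embryo, metabolism, stress responses, chromatin and signalling. The lists, main tests, first set of other settings and rule for named genes were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the lists. Where members are said to pass over the list alone, their edgeR p was adjusted within that list. This does not control for the number of lists or comparisons. A score per library was added after seeing the data: the mean centred log2 CPM of a list's members minus that of all genes kept, compared by exact two-sided permutation of the libraries. Medians of lists were the same with genes at 0 in a group set to the bound of 3 counts. Global distance was the mean Euclidean distance between groups minus that within groups on log2 CPM, divided by the square root of the number of genes and tested by exact one-sided permutation.

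For in vitro against in vivo, the rule for named genes took called genes with a mean CPM of at least 5 and no overlap between in vitro and in vivo libraries, up to 8 of the largest changes in each direction. From each list it took called members with the smallest p, up to 3 where the list passed camera and otherwise 1. For automatic against manual it took all called genes if 10 or fewer, and from each list the member with the smallest p if that was under 0.05 unadjusted. The genes named for in vitro against in vivo were also given for each in vitro group alone. GATA3, CDX2, KRT18, POU5F1, NANOG, SOX2, GATA4, GATA6 and SOX17 were named in any case; other genes that the rule always names are not analysed here. Genes chosen after their values were seen were MSMO1, SC5D and IDI1 for the denudation comparison, LRP2 for automatic against in vivo, and PSPH, PHGDH, PSAT1, ASNS, GARS1, ATF4, PYCR1, SLC38A2, SLC7A11, IFI30, PAG2, SCIN, CRIPTO, KRT19, DAB2, CYP11A1, LUM and POSTN for in vitro against in vivo.

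The tests were tried on simulated counts for 11578 genes, drawn from the real means, dispersions and library sizes, with 50 genes changed at each of 4 fold sizes. For automatic against manual edgeR recovered 0% of 2-fold, 4% of 4-fold, 12% of 8-fold and 28% of 16-fold changes with 0 false calls. For in vitro against in vivo it recovered 2%, 2%, 22% and 28% of the same sizes, with 0 false calls. DESeq2 1.42.0 made 83 false calls in the first simulation and 67 in the second, and voom with quality weights 2 and 3. Camera called the list simulated at a lower level in both, and 0 of 22 others. The simulated genes varied independently of each other, and no low-detection libraries were simulated. The simulation therefore cannot show whether the preset correlation suits the real libraries.

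Other settings tried were other size factors, DESeq2, limma-voom, other filters, fits on the compared groups alone, the replicate number as a block, other thresholds, other distances, and leaving out each library in turn. Added after seeing the data were fits without, or only with, the 5 libraries that had fewer than 9000 genes at 10 or more counts, the logarithm of that gene number as a covariate, and voom with quality weights. A covariate for embryo sex was not run. Figures were drawn with matplotlib 3.10.9.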

Results

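The transcriptomes of bovine blastocysts at day 7 were compared between blastocysts collected in vivo, cultured after manual denudation and cultured after automatic denudation, with 5 libraries in each group. Denudation is the removal of the cumulus cells that surround the oocyte. Library totals were 31.4 ± 8.72 M counts in vivo, 26.4 ± 4.83 M after manual and 28.3 ± 5.67 M after automatic denudation (SD, n = 5 each).

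Epithelial and lineage genes were detected in every group. KRT18, a keratin of the trophectoderm, the outer epithelium of the blastocyst, reached 7245 ± 2081 CPM in vivo, 5769 ± 3601 CPM after manual and 2571 ± 804 CPM after automatic denudation (SD, n = 5). POU5F1, a pluripotency factor, lay at 208 ± 134, 288 ± 140 and 319 ± 164 CPM in the same order, and GATA6, a hypoblast factor, at 226 ± 144, 181 ± 81.6 and 256 ± 221 CPM. The trophectoderm factors GATA3 and CDX2 lay at 61.5 ± 51.5 and 9.78 ± 9.52 CPM in vivo, and SOX2 at 11.2 ± 5.06 CPM. GATA4 and SOX17 were below 1 CPM on average in each group, and SOX17 was too low to be tested.

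Libraries differed widely within groups. In 5 libraries (automatic 2, automatic 4, manual 2, in vivo 2 and in vivo 4) between 6977 and 8547 genes had 10 or more counts, against 9900 to 12611 in the other 10. Transcripts encoded by the mitochondrial genome took 8.18% to 14.4% of counts in these 5 and 3.26% to 9.99% in the others. The first principal component, with 29.6% of the variance, followed the number of genes detected (Pearson r = 0.962 and Spearman rho = 0.975 in absolute value over 15 libraries, permutation p = 1e-05 for each, the smallest these permutations can give). Pearson r was 0.945 without the 2 libraries farthest from the median number of genes, and 0.877 within the 10 other libraries. These 5 libraries are called low-detection libraries.

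**Figure D1:**
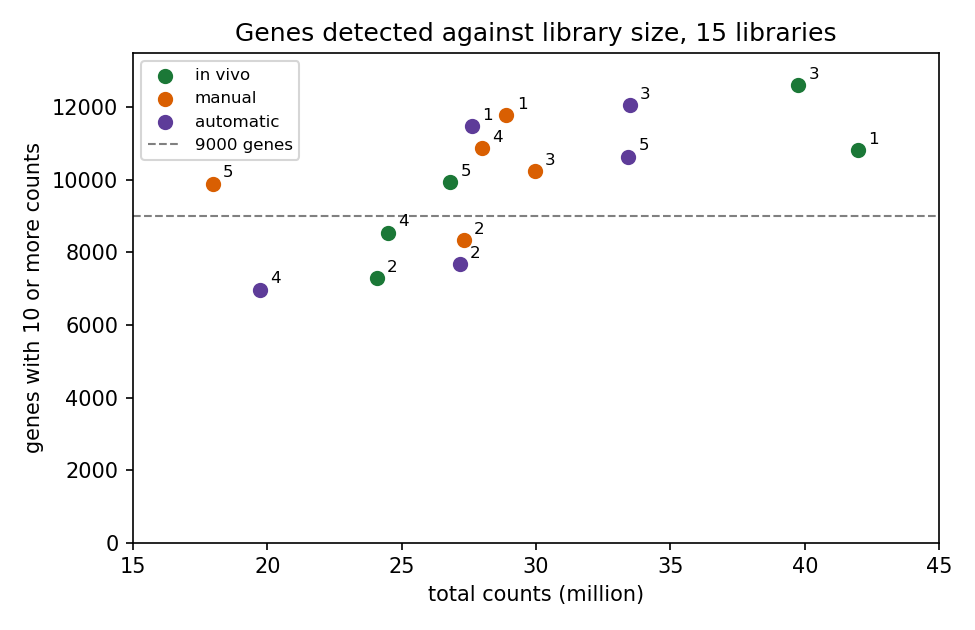
Number of genes with 10 or more counts (y axis) against total counts in M (x axis) for each of the 15 libraries, coloured by group and marked with the replicate number. The 5 libraries under the dashed line at 9000 genes had 6977 to 8547 genes and came from all 3 groups.

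The first comparison asked whether the way the cumulus was removed left a difference in the blastocyst. No single gene passed the test between automatic and manual denudation. Genes of cholesterol synthesis were lower as a group after automatic denudation by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.512 with an estimated correlation). Of 25 measured members 21 lay below their level after manual denudation, with a median log2 difference of -0.98. CYP51A1, which removes a methyl group from lanosterol, lay at 29.3 ± 25.7 CPM after automatic, 171 ± 17.6 CPM after manual denudation and 57.7 ± 57.0 CPM in vivo (SD, n = 5). MSMO1, a sterol oxidase of the pathway, lay at 209 ± 115, 433 ± 103 and 263 ± 149 CPM in the same order, and MSMO1, IDI1 and SC5D differed between automatic and manual by log2 -1.05 ± 0.42, -1.33 ± 0.55 and -1.49 ± 0.62 (SE). For trophectoderm genes, 21 of 24 members were lower after automatic denudation, with a median of -0.80, and the list passed camera with the preset but not with an estimated correlation (adjusted p = 0.512 with an estimated correlation).

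**Figure D2:**
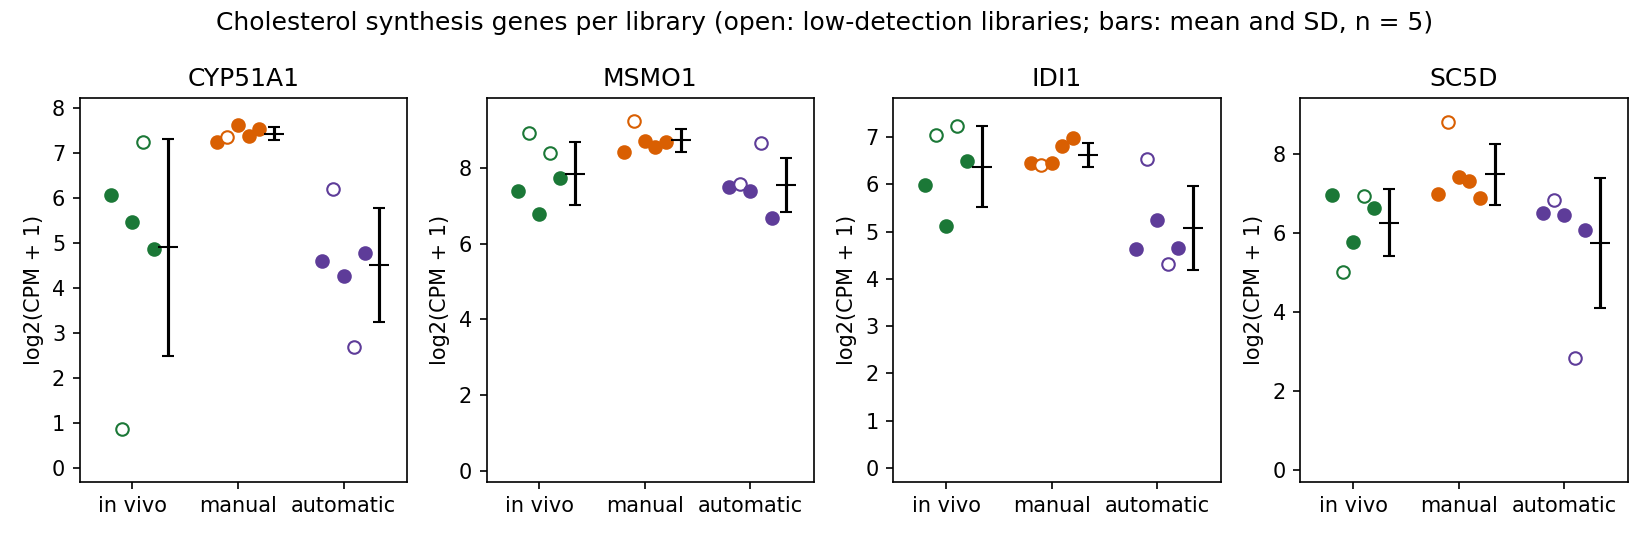
Log2(CPM + 1) of CYP51A1, MSMO1, IDI1 and SC5D (y axes) in each library by group (x axes), with the mean and SD of 5 libraries beside the points and open circles for the low-detection libraries. CYP51A1 was at most 73.0 CPM after automatic and at least 151 CPM after manual denudation.

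By edgeR, 0 of 11578 genes had an adjusted p under 0.05, and 171 had an unadjusted p under 0.05 where 578.9 would be expected by chance. Such a deficit does not show that the groups are alike. The number was 503 without the low-detection libraries (616.45 expected), 429 with the number of detected genes as a covariate and 753 by voom with quality weights. Limma-voom called 0 genes, voom with quality weights 1 and DESeq2 57. Without the low-detection libraries edgeR called 1 gene, CYP51A1 (log2 fold change -2.92 ± 0.38, adjusted p = 0.0363), against -2.55 ± 0.85 with all libraries. By camera the adjusted p was 1.43e-05 for cholesterol synthesis and 2.97e-04 for trophectoderm with the preset correlation (adjusted p = 0.512 with an estimated correlation for each), and 0 members of either passed when adjusted over the list alone. With the low-detection libraries left out, 10 of 25 cholesterol synthesis genes, all lower, passed when adjusted over the list alone, and the list had an adjusted p = 0.0999 with an estimated correlation. The smallest camera adjusted p among the remaining lists was 0.0893, for the inner cell mass and epiblast. The cholesterol synthesis score was -0.51 ± 1.12 after automatic denudation, 0.58 ± 0.49 after manual denudation and -0.07 ± 1.01 in vivo (SD, n = 5). Between automatic and manual it differed by -1.09 (exact permutation p = 0.0952, adjusted p = 0.730 over 23 lists). The trophectoderm score differed by -0.92 (exact permutation p = 0.00794, the smallest that 252 splits can give, adjusted p = 0.183). A single list at that p cannot pass over 23 lists. The 95% interval of the fold change lay within 2-fold for 380 genes (3.28%) and within 4-fold for 2776 genes (24.0%), so differences of those sizes could not be excluded for most genes.

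The member with the smallest p of a list, named only where that p was under 0.05 unadjusted, gave values in both directions. Lists without such a member are not shown here. LRP2, an endocytic receptor in the hypoblast list, differed by log2 -1.26 ± 0.30 and was the 1 gene of its list to pass when adjusted over the list alone. Values below 0 were also found for KRT18 at -1.17 ± 0.35, AKR1B1 (an aldose reductase) at -1.21 ± 0.38, SCD (a fatty acid desaturase) at -2.13 ± 0.67, HSD3B1 (a steroid dehydrogenase) at -1.77 ± 0.65, DSC2 (a desmosomal cadherin) at -1.77 ± 0.79, LGALS3 at -0.84 ± 0.29 and SLC16A1 (a lactate transporter) at -0.82 ± 0.37. Values above 0 were found for KIT at 1.17 ± 0.50 and RRM2, a subunit of ribonucleotide reductase, at 0.82 ± 0.30. By edgeR over all genes the adjusted p of each was 0.9999. IFI6, an interferon-induced gene, lay at 50.2 ± 71.3 CPM after manual and 0.129 ± 0.245 CPM after automatic denudation, and TNFRSF1A at 7.83 ± 10.2 and 0.105 ± 0.175 CPM. For both genes 0 of 5 automatic libraries lay below the lowest manual library. TNFRSF1A had 0 counts in 2 of 5 manual libraries. Over fits without 1 library the edgeR adjusted p of both genes was at least 0.9997. NODAL had counts in 1 manual library and 0 in the automatic libraries. The lineage factors GATA3, CDX2, POU5F1, NANOG, SOX2, GATA4 and GATA6 differed by log2 -0.40 ± 0.77, -0.90 ± 1.30, 0.15 ± 0.54, -0.15 ± 0.59, 0.83 ± 0.88, -0.60 ± 1.67 and 0.50 ± 0.56. Over fits without 1 library they ranged from -0.88 to -0.10, -1.33 to -0.49, -0.11 to 0.49, -0.52 to 0.23, 0.14 to 1.13, -2.37 to -0.25 and -0.15 to 0.78 in that order, KRT18 was at -0.69 without manual 3 and SC5D at -0.97 without manual 2. Cumulus and granulosa cell genes did not pass camera (adjusted p = 0.291, 10 of 13 lower after automatic denudation).

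Over whole transcriptomes, the mean distance between the automatic and manual groups minus that within groups was -0.06 (one-sided exact permutation p = 0.619, 252 splits). Leaving out automatic 1, automatic 3 or automatic 5 turned it to 0.0466, 0.0643 and 0.0162 (exact permutation p of at least 0.254). Centring the libraries within each replicate number turned it to 0.162 (exact permutation p = 0.0476). That centring sets the libraries of a number opposite each other, while the splits did not keep them apart. This p therefore does not measure denudation alone.

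The second comparison set blastocysts from in vitro culture against those collected in vivo. Genes of the amino acid response and of amino acid transport were higher in vitro as a group by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.204 with an estimated correlation). Of 31 measured members 26 were higher, with a median log2 difference of 1.01. CHAC1, which degrades glutathione and is induced by amino acid shortage, lay at 17.9 ± 12.5 CPM after manual and 24.3 ± 9.13 CPM after automatic denudation, and had 5 counts in 1 in vivo library and 0 in the other 4. PSPH, the last enzyme of serine synthesis, lay at 149 ± 46.6 and 200 ± 87.8 CPM in the same groups and at 4.85 ± 4.75 CPM in vivo. ASNS, asparagine synthetase, lay at 353 ± 202, 540 ± 394 and 70.9 ± 40.3 CPM after manual denudation, after automatic denudation and in vivo. For CHAC1, PSPH and ASNS all 10 in vitro libraries lay above all 5 in vivo libraries. This separation is no test: the rule for the largest changes asked for it, and PSPH and ASNS were chosen after their values were seen. PAGE4 was lower in vitro, at 19.99 ± 12.2 and 10.01 ± 5.76 CPM against 155 ± 74.9 CPM in vivo.

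**Figure D3:**
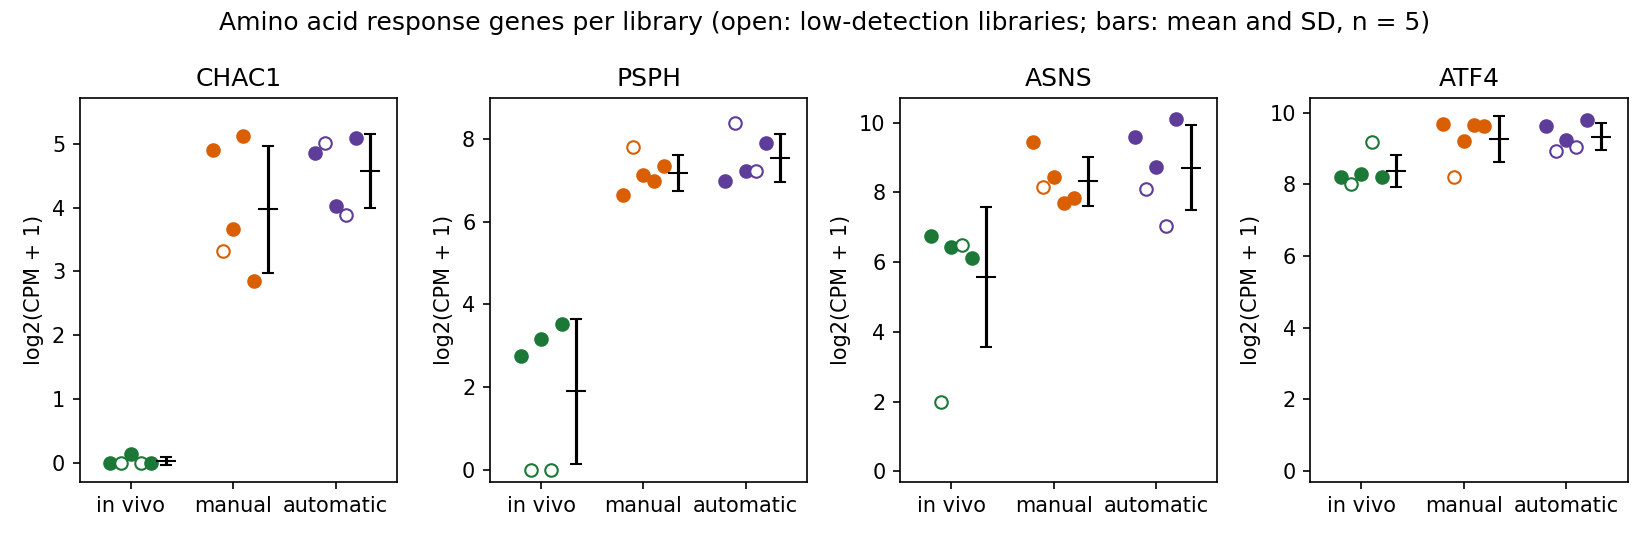
Log2(CPM + 1) of CHAC1, PSPH, ASNS and ATF4 (y axes) in each library by group (x axes), with the mean and SD of 5 libraries beside the points and open circles for the low-detection libraries. For CHAC1, PSPH and ASNS the 10 in vitro libraries lay above the 5 in vivo libraries, and for ATF4 7 of 10 did. PSPH, ASNS and ATF4 were chosen after their values were seen.

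By edgeR 2 of 11578 genes were called, CHAC1 (log2 fold change 9.49 ± 1.55, adjusted p = 0.0415) and PAGE4 (-3.46 ± 0.55, adjusted p = 0.0415), and 710 genes had an unadjusted p under 0.05 where 578.9 would be expected. The fitted fold change of CHAC1 rests on in vivo counts near 0. Both calls were kept in 2 of 15 fits that left out 1 library (without automatic 4 and without manual 3), and elsewhere the adjusted p reached 0.265 for each. Scaling by library size in place of TMM ended both calls, as it did those of automatic denudation against in vivo. With the replicate number as a block CHAC1 was called neither here nor for automatic denudation against in vivo. Without the low-detection libraries 7 genes were called by edgeR: PSPH, PHGDH, PSAT1 and CHAC1 higher, and IFI30, PAG2 and SCIN lower, with PAGE4 at an adjusted p = 0.0802. In that fit PSPH differed by log2 4.22 ± 0.39 (adjusted p = 8.88e-04), PHGDH by 4.17 ± 0.51 (adjusted p = 0.0105) and PSAT1 by 2.26 ± 0.32 (adjusted p = 0.0310), and these 3 genes make up the serine synthesis pathway. With all libraries PSPH differed by 5.15 ± 1.08, PHGDH by 1.02 ± 1.21 and PSAT1 by 0.76 ± 0.50. Leaving out in vivo 2 alone gave 4.27 for PHGDH (edgeR adjusted p = 0.474) and 1.88 for PSAT1 (edgeR adjusted p = 0.146). IFI30 lay at 41.97 ± 18.7 and 3.69 ± 3.54 CPM after manual and automatic denudation and 99.7 ± 72.9 CPM in vivo, and SCIN at 62.8 ± 29.3, 17.8 ± 12.2 and 156 ± 111 CPM.

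The amino acid list had a camera adjusted p of 3.46e-09 with the preset correlation, and adjusted p = 0.204 with an estimated correlation. Adjusted over the list alone 7 members passed, all higher: CHAC1, PSPH, ASNS (log2 2.62 ± 0.65), ATF4 (0.93 ± 0.30), PYCR1 (4.53 ± 1.30), SLC38A2 (1.01 ± 0.30) and SLC7A11. Of these only CHAC1 was called over all genes with all libraries. ATF4 is a transcription factor of the response, PYCR1 makes proline, and SLC38A2 and SLC7A11 are amino acid carriers. SLC7A11 had 0 counts in vivo and lay at 2.02 ± 2.996 CPM after manual and 8.48 ± 11.7 CPM after automatic denudation. It had counts in only 5 of 10 in vitro libraries. GARS1, a tRNA synthetase, differed by 1.06 ± 0.37. The mean list score was 0.63 ± 0.65 after automatic denudation, 0.62 ± 0.16 after manual denudation and -1.25 ± 0.28 in vivo (SD, n = 5), a difference of 1.87 between in vitro and in vivo libraries (exact permutation p = 0.000333, the smallest that 3003 splits can give, adjusted p = 0.00766 over 23 lists). Without the low-detection libraries the list had an adjusted p = 0.0074 with an estimated correlation, and 13 of 33 members passed when adjusted over the list alone.

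**Figure D4:**
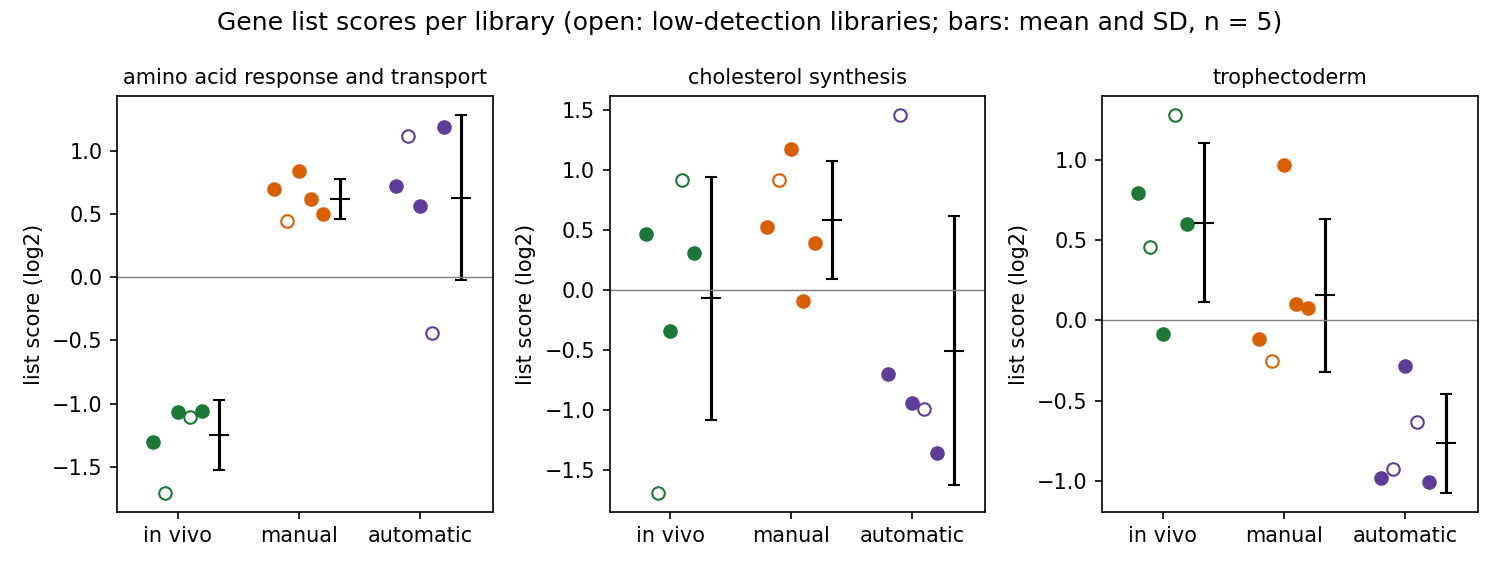
Scores of the amino acid response and transport, cholesterol synthesis and trophectoderm lists (y axes, log2 scale) in each library by group (x axes), with the mean and SD of 5 libraries and open circles for the low-detection libraries. For the amino acid list all 10 in vitro libraries lay above all 5 in vivo libraries.

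For in vitro against in vivo 18 of 24 trophectoderm genes were lower (median -0.76, camera adjusted p = 0.00161, and adjusted p = 0.977 with an estimated correlation). Set singly against in vivo, the list passed camera after automatic denudation (median -1.16, adjusted p = 1.97e-05, and adjusted p = 0.430 with an estimated correlation) and not after manual denudation (median -0.41, adjusted p = 0.208). Its score was -0.76 ± 0.31 after automatic denudation, 0.16 ± 0.48 after manual denudation and 0.61 ± 0.49 in vivo (SD, n = 5). Between in vitro and in vivo the score differed by -0.91 (exact permutation p = 0.0143, adjusted p = 0.110), and by -0.61 (exact permutation p = 0.192) with the low-detection libraries left out. Without these libraries camera gave an adjusted p of 2.69e-04 with the preset correlation, and the list did not pass with an estimated correlation. PAG2 lay at 56.2 ± 45.9, 221 ± 118 and 536 ± 214 CPM and KRT19 at 264 ± 90.3, 1014 ± 929 and 1855 ± 1411 CPM after automatic denudation, after manual denudation and in vivo. Adjusted over the list alone 5 members passed for in vitro against in vivo, all lower: PAG2, a pregnancy-associated glycoprotein (-2.27 ± 0.58), KRT18 (-0.91 ± 0.29), KRT19 (-1.84 ± 0.55), DAB2 (-0.95 ± 0.28) and CYP11A1 (-2.29 ± 0.72). None of them was called over all genes with all libraries. Nuclear genes of oxidative phosphorylation were lower by camera (58 of 69, median -0.45, adjusted p = 0.0025, and adjusted p = 0.988 with an estimated correlation). That call was lost without automatic 1, automatic 3, in vivo 2 or in vivo 4, with an adjusted p = 0.565 without in vivo 2. Maternal oocyte transcripts were higher by camera (12 of 16, median 1.23, adjusted p = 0.0449, and adjusted p = 0.977 with an estimated correlation), and did not pass for manual denudation alone (adjusted p = 0.208). That call was lost without automatic 2, automatic 3, in vivo 1, in vivo 3 or in vivo 5, with an adjusted p of at most 0.0895, and under the filter of 1 CPM in 5 libraries. NANOG, a pluripotency factor, lay at 54.5 ± 32.0 and 49.0 ± 32.3 CPM after manual and automatic denudation and 264 ± 111 CPM in vivo (log2 -2.35 ± 0.49, edgeR adjusted p = 0.191), with all 10 in vitro libraries below all 5 in vivo libraries. It was among 2 of 23 epiblast genes, both lower, that passed when adjusted over the list alone, while that list did not pass camera (adjusted p = 0.930). CRIPTO, a NODAL co-receptor, differed by -6.20 ± 1.45 (edgeR adjusted p = 0.275). GATA3, CDX2, POU5F1, SOX2, GATA4 and GATA6 differed by 0.46 ± 0.68, -0.77 ± 1.09, 0.54 ± 0.48, 1.21 ± 0.80, -0.59 ± 1.41 and -0.07 ± 0.48, and GATA6 was at 0.24 when scaled by library size alone, which moved the median of all genes from -0.04 to 0.10. Over fits without 1 library GATA3 ranged from 0.20 to 0.88, CDX2 from -1.03 to 0.06, POU5F1 from 0.26 to 0.85, GATA4 from -1.48 to -0.04 and GATA6 from -0.39 to 0.38. Cumulus and granulosa cell genes did not pass camera (adjusted p = 0.930), and the smallest adjusted p among the remaining lists was 0.118, for apoptosis and p53 targets.

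Set singly against in vivo, automatic denudation differed in 2 genes by edgeR, CHAC1 (9.71 ± 1.59, adjusted p = 0.0424) and LRP2 (-2.04 ± 0.31, adjusted p = 0.0294). LRP2 lay at 709 ± 168 CPM after automatic denudation, 1692 ± 669 CPM after manual denudation and 2907 ± 753 CPM in vivo. PAGE4 differed by -3.96 ± 0.73 (edgeR adjusted p = 0.117). Manual denudation differed from in vivo in 0 genes by edgeR, with 392 genes at an unadjusted p under 0.05; limma-voom called 1, voom with quality weights 2 and DESeq2 115. CHAC1 differed there by 9.27 ± 1.57 (edgeR adjusted p = 0.124) and PAGE4 by -2.96 ± 0.69 (edgeR adjusted p = 0.705). Without the low-detection libraries edgeR called 9 genes for automatic denudation, with CHAC1 but not LRP2 (-1.84 ± 0.33, adjusted p = 0.113) among them, and 3 for manual denudation. The calls for automatic denudation were kept in 2 of 15 fits without 1 library for CHAC1 (without manual 3 and without in vivo 3, elsewhere up to an adjusted p = 0.210) and in 6 of 15 for LRP2 (without automatic 3, manual 1, manual 2, manual 3, in vivo 2 and in vivo 3, elsewhere up to 0.161). The CHAC1 call for automatic denudation also ended without a filter on low counts and with only the compared groups in the fit, where LRP2 was the 1 gene called. The difference between the effects of both methods is the test of automatic against manual, in which edgeR called 0 genes.

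Over whole transcriptomes, the distance between in vitro and in vivo libraries minus that within groups was 0.07 (one-sided exact permutation p = 0.314, 3003 splits), and -0.09 without in vivo 2 (exact permutation p = 0.560).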

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

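Chosen after the result was seen were the tests of library size and of group for the low-detection libraries, both tests that left these libraries out, the permutation p of the cholesterol synthesis score, and the fits without these libraries or with quality weights.

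Of 156 groups of 5 libraries tested for a library far from the rest, 24 had one. For independent and normally spread values chance gives about 1 in 20 groups (7.8). For SOX17, NODAL and CHAC1 counts in a single library of the group made the flag certain. Many of the genes were chosen after their values were seen. The excess over 7.8 is therefore not a measured excess of outlying libraries. In total counts manual 5 stood low at 17.96 M. On the log2(CPM + 1) scale, manual 3 stood high for KRT18 (13.6) and SOX17 (0.0885), manual 1 for NODAL (1.48), and manual 2 high for KIT (7.46) and SC5D (8.83) and low for SCD (5.76). Automatic 3 stood high for LRP2 (9.97) and SOX17 (0.284), and automatic 1 high for IFI6 (0.644) and low for LGALS3 (10.4). Automatic 4 stood low for SC5D (2.85) and PHGDH (0), and automatic 2 low for SCIN (0). In vivo 2 stood low for ASNS (1.99) and IFI30 (0) and high for GARS1 (8.57), in vivo 3 low for LGALS3 (11.6) and CYP11A1 (4.80) and high for CHAC1 (0.140), in vivo 4 high for ATF4 (9.17), and in vivo 5 low for SCD (3.88). Among list scores, automatic 2 stood high for cholesterol synthesis (1.45) and manual 3 for trophectoderm (0.969).

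In automatic against manual, which is the difference between both in vitro effects, camera with a preset correlation gave an adjusted p = 2.97e-04 for the trophectoderm list and 1.43e-05 for the cholesterol synthesis list. Neither passed with an estimated correlation (adjusted p = 0.512 for each) or by exact permutation of the scores (adjusted p = 0.183 and 0.730), and 66 of 100 splits gave as many lists.

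In the 5 low-detection libraries few genes were detected. Library size is argued against as the cause, since with every library thinned to the smallest total the highest of them reached 8351 genes and the lowest of the others 9690. Experimental group is argued against as well, since 3 of 3 groups held both kinds of library. By replicate number the 5 were not scattered: they were number 2 of each group, and number 4 of the automatic and in vivo groups. Manual 4 was among the others. The labels do not say what a number marks, and a cause shared by number was not tested. Random loss of transcripts during library preparation stays open: of 5848 genes with at least 100 counts in each other library, 152 to 567 had 0 counts in a low-detection library, and pairs of these libraries shared a median of 1.70 times the number expected at their expression, between the values under 1.5 and over 2 set beforehand for and against it. No biological explanation other than group was tested.

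The amino acid response was higher in vitro (camera adjusted p = 0.204 with an estimated correlation). The low-detection libraries are argued against as the cause, since without them the score difference was 1.87 (exact permutation p = 0.00833, the smallest that 120 splits can give, adjusted p = 0.192 over 23 lists), and so is library size, since with equal totals it was 1.76 (exact permutation p = 0.000333, the smallest possible). The score of 10 tRNA synthetases described as ATF4 targets, none of them in the list and leaving out 3 whose values had been seen, was 0.824 higher in vitro (exact permutation p = 0.00433), and that of 7 other synthetases differed by -0.147 (exact permutation p = 0.617). As a hypothesis, this is consistent with an ATF4 programme in cultured blastocysts. The difference between the ATF4-target and the other synthetases was not tested. Their scores therefore do not show a rise particular to ATF4 targets. In vitro culture, collection and handling differ together between the groups and were not tested apart.

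Cholesterol synthesis genes were lower after automatic than manual denudation (camera adjusted p = 0.512 with an estimated correlation). The low-detection libraries are argued against as the cause, since without them the score difference was -1.50 (exact permutation p = 0.0286, the smallest that 35 splits can give, adjusted p = 0.329 over 23 lists). Library size is argued against, since with equal totals the difference was -1.06 (exact permutation p = 0.0873), over 0.5 of its size. A chance difference between libraries cannot be told apart from an effect of denudation, because the permutation p over all libraries was 0.0952 and automatic 2 had the highest score of the 15 libraries. The denudation method itself stays open as an explanation.

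Other splits of the same libraries were fitted for the counts below, and for no count of limma-voom nor those of DESeq2 and voom with quality weights in automatic or manual against in vivo. By edgeR, 1 of 100 splits, the real one, gave as many as the 2 genes of in vitro against in vivo (highest other 0). The same held for the 2 genes of automatic against in vivo (1 of 100, highest other 0). Without the low-detection libraries it also held for the 7 genes of in vitro against in vivo (1 of 100, highest other 1). These shares are under 0.05 and the smallest that 100 splits can give. The splits were drawn from 3003, 126 and 120 possible ones in that order. The shares were not adjusted for the number of counts tried, so chance is not taken as excluded. For the 0 genes of automatic against manual and of manual against in vivo, 100 of 100 splits gave as many, with 0 as the highest other. For the 1 gene of automatic against manual without the low-detection libraries 3 of 35 splits did (highest other 9), so chance cannot be excluded. Without these libraries 1 of 35 splits, the real one, gave as many as the 3 genes of manual against in vivo (highest other 2). That is the smallest share 35 splits can give, and the subset was chosen after seeing the data. Chance is therefore not taken as excluded there. Automatic against in vivo has 10 splits without these libraries, too few for a share under 0.05. It had 9 genes (highest other 0) and 6 lists (highest other 6). Chance cannot be excluded for the other counts of lists by camera: 66 of 100 splits gave as many as the 2 lists of automatic against manual, 17 of 100 as many as the 4 of in vitro against in vivo, 8 of 100 as many as the 4 of automatic and 45 of 100 as many as the 3 of manual against in vivo (highest other 7 in each). Without the low-detection libraries 6 of 35 splits gave as many as the 7 lists of automatic against manual (highest other 10), 34 of 100 as many as the 5 of in vitro against in vivo (highest other 11) and 15 of 35 as many as the 4 of manual against in vivo (highest other 8). By DESeq2 chance cannot be excluded, with 11 of 21 splits reaching the 57 genes of automatic against manual (highest other 297) and 2 of 21 the 197 genes of in vitro against in vivo (highest other 530). By voom with quality weights 11 of 60 splits reached the 1 gene of automatic against manual (highest other 474), so chance cannot be excluded, and 2 of 60 reached the 106 genes of in vitro against in vivo. There 1 other split exceeded the real count (highest other 168) and only 60 of 3003 splits were drawn, so chance is not taken as excluded. Splits with several times the real count may come from a structure of the libraries other than the groups, which was not tested, and for DESeq2 also from its false calls, of which simulated counts gave 83 and 67.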

How the results depend on the processing

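Fits without or only with the low-detection libraries, with a detection covariate or with voom quality weights, and the permutation of list scores, were chosen after seeing the data; the covariate for embryo sex was not run. The cause was not tested for any change below, except that subsets of libraries hold fewer samples. The spread limits all counts, with a median SE of 1.26 for automatic against manual.

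Counts are given for automatic against manual, in vitro against in vivo, automatic against in vivo and manual against in vivo, where edgeR called 0, 2, 2 and 0 genes. DESeq2 called 57, 197, 169 and 115, limma-voom 0, 15, 9 and 1, and voom with quality weights 1, 106, 94 and 2. Without the low-detection libraries 1, 7, 9 and 3 were called, with only these libraries 0, 4, 9 and 1, and with the detection covariate 0, 7, 3 and 0. Library size alone and an adjusted p under 0.01 gave 0 in each. Automatic against in vivo gave 1 gene without a filter and 1 with only the compared groups in the fit, LRP2 in both, so that CHAC1 was lost. Leaving out each library gave 0 to 7 genes for in vitro against in vivo (7 without manual 3, 2 without automatic 4, 0 without any other), 0 to 4 for automatic against in vivo (4 without manual 3, 2 without in vivo 3, 1 without automatic 3, manual 1, manual 2 or in vivo 2, 0 without any other) and 0 for the others.

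Same-numbered libraries had residual correlations of 0.00137 to 0.380, with 8 of 15 pairs over 0.1. Among libraries of the other groups, of which only a minority carry the same number, 8 of 15 libraries correlated best with their own number. Among all pairs automatic 1 and manual 1 had the highest Spearman correlation, 0.947 against at most 0.931 within a group. These values go with a structure shared by number, although manual 1 and in vivo 3 also reached a residual correlation of 0.370. Such a structure is not excluded, and its cause was not tested. The labels do not say what a number marks, so the main fit has no block and the permutations treat the libraries as unpaired. With the replicate block 0, 8, 7 and 1 genes were called, all of them lower, so that CHAC1 was no longer called for in vitro or automatic against in vivo, and 1 gene was shared with the fit without the block in each of these. The distance of automatic from manual with that block was 0.162 (exact permutation p = 0.0476). The splits behind this p did not keep same-numbered libraries apart, although the centring sets them opposite each other. It therefore does not measure denudation alone.

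For lists, automatic against manual had 2, with an estimated correlation 0, by fry 0, with permuted scores 0, without the low-detection libraries 7, with only them 0, and 2 to 6 over fits without 1 library (6 without manual 2, 5 without automatic 2, 4 without manual 5, 2 or 3 otherwise). In vitro against in vivo had 4, with an estimated correlation 0, by fry 1, with permuted scores 1, with only the low-detection libraries 0, and 2 to 4 without 1 library (2 without automatic 3). Without 1 library the distance was -0.149 to 0.0643 for automatic against manual (above 0 without automatic 1, automatic 3 or automatic 5) and -0.0902 to 0.212 for in vitro against in vivo (below 0 without in vivo 2).

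Of 1532 values of named genes 1397 kept direction and side of the threshold, 62 lost and 45 gained a call, and 28 changed sign or, for NODAL in 2 fits, were exactly 0. For automatic against manual, values without the low-detection libraries were 0.0019 for GATA3, -0.23 for POU5F1, -0.23 for SOX2 and -0.34 for GATA6, and with quality weights 0.041, -0.33, -0.49 and -0.48, with 0.12 for NANOG. With only the low-detection libraries NANOG was at 0.019 and NODAL at 0, and for in vitro against in vivo PHGDH at -1.12, PSAT1 at -0.45 and ATF4 at -0.10. GATA6 in vitro against in vivo was 0.24 by library size alone, 0.18 without the low-detection libraries and 0.022 with the covariate. Without 1 library, automatic against manual ranged from -0.11 to 0.49 for POU5F1, -0.52 to 0.23 for NANOG, -0.15 to 0.78 for GATA6 and -6.79 to 0 for NODAL, and in vitro against in vivo from -1.03 to 0.058 for CDX2 and -0.39 to 0.38 for GATA6.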

Other observations

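The genes in this part were chosen after their values were seen. LUM and POSTN, which encode extracellular matrix proteins of connective tissue, were nearly absent in vivo and variable in vitro. LUM lay at 65.2 ± 61.2 CPM after manual and 23.3 ± 32.3 CPM after automatic denudation and at 0.102 ± 0.149 CPM in vivo (SD, n = 5). POSTN lay at 103 ± 138 and 21.4 ± 33.8 CPM in the same groups and had 0 counts in vivo. Neither was called over all genes (edgeR adjusted p = 0.275 for LUM and for POSTN). LUM belongs to the list of cumulus and granulosa cell genes and was the 1 higher of 2 members that passed when adjusted over the list alone, while 8 of the 13 members were lower in vitro, the median was -0.50 and the mean 0.34, and the list did not pass camera (adjusted p = 0.930).

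Antioxidant genes and targets of the stress-responsive factor NRF2 went both ways between in vitro and in vivo. Adjusted over the list alone 7 of 35 passed, 2 higher and 5 lower in vitro, while the list had a median of -0.14 and a mean of 0.15 and did not pass camera (adjusted p = 0.655).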
